A study of Mus musculus with 2 samples.

How the data were processed

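The data are unique molecular identifier (UMI) counts per gene and barcode from 10x Chromium 3' libraries of sorted tdTomato-positive islet cells. The authors deposited whole-number counts, not normalized, for 46983 genes, per the labels and the values. The submitters' processing notes name STARsolo, STAR 2.7.3a, Seurat 4.3.0.1 and the build GRCm38.p6, and the role of Seurat is not given in the sources used here. Each genotype is 1 library pooled from 6 animals, and actinomycin D, a transcription inhibitor, was present during dissociation, per the labels' protocols. The control matrix listed 6794880 barcodes, of which 1919728 held a UMI, with 89375215 UMIs in all. The Isl1CKO matrix listed 3020 barcodes, the lowest with 4882 UMIs, and 78068592 UMIs, so it had been filtered before deposit and the control matrix had not.

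Control barcodes were taken as cells when they held at least 1/10 of the 99th percentile of the top 3000 barcodes, a threshold of 6825 UMIs that 2504 barcodes passed. All 3020 Isl1CKO barcodes were kept at this step. In addition 872 control barcodes with at least 1000 UMIs lay below the threshold, with a median mitochondrial share of 20.4%. Cells needed at least 1000 UMIs, 500 genes and at most 15% mitochondrial UMIs, which left 2496 control and 2987 Isl1CKO cells. Scrublet, run in scanpy 1.11.5 with an expected rate of 0.8% per 1000 cells, called 62 control doublets (2.48%) and 4 Isl1CKO doublets (0.134%). The Isl1CKO calls are far below the expected rate, so doublets may remain in that library.

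Counts were scaled to 10000 per cell and logged. The 2000 most variable genes, without mitochondrial, ribosomal, haemoglobin, Xist, Y-linked and some abundant noncoding genes, gave 30 principal components and a graph of 15 neighbours, clustered by Leiden at resolution 1 with igraph 0.11.9. Markers of 15 cell types and 18 gene lists were fixed before the data were examined. The scoring rule was set after the data were seen. A cluster took the name of the type with the largest share of markers at least 2-fold over all other cells, with at least 3 markers and the type's lead gene, such as Gcg for alpha cells, where 1 was set. No other type could have more markers among its top 10 genes, and a non-endocrine type needed 3 there. The other 10 clusters stayed unnamed.

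UMIs were summed per library over all cells and over beta-like cells, the only named class with at least 50 cells in both libraries, and scaled to the total (CPM). Genes with at least 50 UMIs in the library with the higher CPM were compared. Where the sums differ in size, this minimum asks a higher CPM of genes that are higher in the smaller sum. With 1 library per genotype no test was run. Ratios carry exact conditional binomial intervals, sums exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals at 95%, all for counting error only. A gene with 0 UMIs in 1 library is given against a floor of 3 UMIs. Genes are counted by a fixed size rule, a CPM ratio of at least 2. Because hormones take a large part of the UMIs, ratios are given relative to the median gene. Each gene list is described by its median and the percentile of that median among 10000 random lists matched on mean expression in 20 bins.

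Named genes are the 10 with the highest and the 10 with the lowest ratio per comparison, ranked by the interval bound nearest to 0, leaving out mitochondrial, ribosomal, uncharacterised, Xist, Y-linked, acinar and erythroid genes, plus members of the fixed lists and Isl1. Coordinates come from GENCODE M21 on GRCm38, which holds 46488 of the 46983 gene identifiers. The annotation release used for counting is not given in the sources used here. Neurod1 shares exon sequence on its strand with Cerkl, and Manf with Rbm15b, so their counts are uncertain. Results for some genes are left out because those genes were withheld.

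The comparison was tested on counts simulated from the control profile with counting error only and 200 genes changed. Changed genes were taken below the most abundant ones, so that the totals hardly moved. The rates that follow therefore cover neither the shift in hormone share between the libraries nor variation between pools. Over all cells, 100% of genes with a true 4-fold difference and 96% to 98% of those with a 2.4-fold one passed the size rule among 13677 genes, and 0.0223% of unchanged genes did. In beta-like cells, 100% and 86% to 97.9% passed among 9618 genes, and 0.212% of unchanged genes did. The alternatives varied the barcode rule, the mitochondrial filter, doublets, cells with several hormones, clustering, depth, sex of cells, scaling, background and the minimum count. Cells with several hormones were those in which several hormone types each made up at least 5% of the cell's own islet hormone UMIs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.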

Results

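Islet cells of 9-day-old mice were profiled by droplet single-cell RNA sequencing after sorting for the tdTomato reporter. Isl1 encodes a LIM-homeodomain transcription factor of islet endocrine cells, and the design asks what its conditional deletion through a Neurod1-driven Cre does to the endocrine lineages. The labels give both libraries 1 Neurod1 Cre allele (Neurod1 Cre/+). The control library carried 1 floxed Isl1 allele (Isl1f/+) and the library labelled Isl1CKO carried 2 (Isl1f/f). The control can thus have lost Isl1 on 1 allele, and is neither free of Cre nor known to be intact for Isl1. Each library pooled 6 animals, so each genotype has 1 library and no difference has a replicate check. After filtering, 2434 control cells with 69799050 UMIs and 2983 Isl1CKO cells with 77645650 UMIs remained. Median depth was 22457 UMIs and 4109 genes per control cell, and 25027 UMIs and 4786 genes per Isl1CKO cell. All intervals are exact 95% intervals that cover counting error only.

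Isl1 transcripts were still counted in the library labelled Isl1CKO. Over all cells, Isl1 (ENSMUSG00000042258, GRCm38 chromosome 13, 116298281 to 116309689, minus strand) stood at 253 CPM in the control library (249 to 257) and 459 CPM in the Isl1CKO-labelled library (454 to 463). Computed over UMIs outside the islet hormones the levels were 542 and 522 CPM. In beta-like cells Isl1 was 79.9 CPM in the control and 180 CPM in the Isl1CKO-labelled library. In the beta-like cluster that both libraries share it was 47.4 and 180 CPM. Control alpha-like cells held 472 CPM and control delta-like cells 711 CPM. The labels do not say which exon is floxed, so 3' tags can lie outside the deleted part, and these counts check neither the deletion nor the label.

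Islet hormones took very different shares of the transcripts in the 2 libraries. Islet hormone transcripts made up 53.3% of all UMIs in control cells and 12.2% in Isl1CKO cells, with medians per cell of 36.6% and 0.632%. Cells with hormones below 1% of their UMIs were 3.41% of the control library (2.73 to 4.21) and 58.1% of the Isl1CKO library (56.3 to 59.8). Gcg, which encodes glucagon, was 54637 CPM in control cells and 1189 CPM in Isl1CKO cells. Sst, the somatostatin gene, was 14954 against 126 CPM, and Ppy, the pancreatic polypeptide gene, was 21005 against 312 CPM. The insulin genes were also lower, Ins1 at 128547 against 42888 CPM and Ins2 at 255371 against 62085 CPM. Iapp, the islet amyloid gene, was 24148 against 11376 CPM, and Pyy, the peptide YY gene, 34456 against 3347 CPM. Ghrl, the ghrelin gene, was 349 CPM in control and 721 CPM in Isl1CKO cells, but 749 and 822 CPM over non-hormone UMIs, so most of its difference goes with the scaling.

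**Figure D1:**
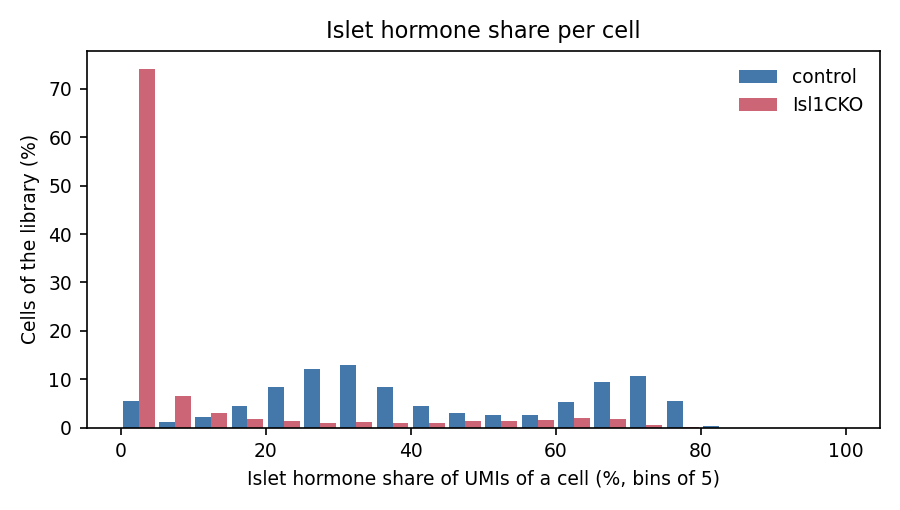
Percent of cells in each library (vertical axis) by the islet hormone share of a cell's UMIs (horizontal axis, percent, bins of 5). Cells with hormones below 5% of UMIs are 5.55% of the control library and 74.1% of the Isl1CKO library.

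Counted by hormone, cells with Gcg at 5% or more of their UMIs made up 26.1% of the control library (24.4 to 27.9) and 0.067% of the Isl1CKO library (0.00812 to 0.242). Cells passing the same level of Sst made up 21.7% of control and 0.201% of Isl1CKO cells, and those passing it for Ppy 17.2% and 0.101%. Cells with insulin transcripts at 5% or more were 36.3% of control (34.4 to 38.3) and 19.2% of Isl1CKO cells (17.8 to 20.6). Mesenchymal-like cells, which should lack these hormones, gave 0 of 58 control cells above that level for Gcg, which allows a share of up to 6.16%. For insulin transcripts 0 of 58 control and 1 of 29 Isl1CKO mesenchymal-like cells passed, the latter a share of 3.45% (up to 17.8%). Median depth of the control mesenchymal-like cells was 9284.5 UMIs, below the 22457 UMIs of all control cells.

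Clustering of both libraries together gave 17 clusters, of which 7 could be named from fixed markers. Beta-like clusters held 34.4% of control cells (32.5 to 36.4) and 12.3% of Isl1CKO cells (11.1 to 13.5). The alpha-like cluster, led by Gcg, held 24.3% of control and 0.134% of Isl1CKO cells. The delta-like cluster, with Sst and the delta-cell regulator Hhex, held 24.7% and 0.268%. With the hormones left out of clustering, beta-like cells were 35.0% and 12.1%, alpha-like cells 24.4% and 0.369%, and delta-like cells 24.5% and 0.335%. A name still needed the lead hormone gene in that setting, so Gcg-poor or Sst-poor clusters could not be called alpha-like or delta-like. These shares therefore do not separate a loss of cells from a loss of hormone transcripts. Across all settings beta-like shares ran from 29.0% to 61.5% in control and from 0.771% to 28.9% in Isl1CKO cells, and the control delta-like share from 0.150% to 24.8%. Clusters without a name held 14.0% of control and 86.0% of Isl1CKO cells, and because several belong almost wholly to 1 library, they may be that library and not a type. Among them, 4 clusters with alpha markers such as Irx1, Irx2, Gc and Ttr held 23 control and 1527 Isl1CKO cells, under a naming rule set after the data were seen. Gcg was 1838 CPM in their Isl1CKO cells, the Gcg-low cells, and 151678 CPM in their control cells. Mesenchymal-like cells made up 2.38% of control and 0.972% of Isl1CKO cells, and acinar-like cells 0.205% and 0.302%.

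**Figure D2:**
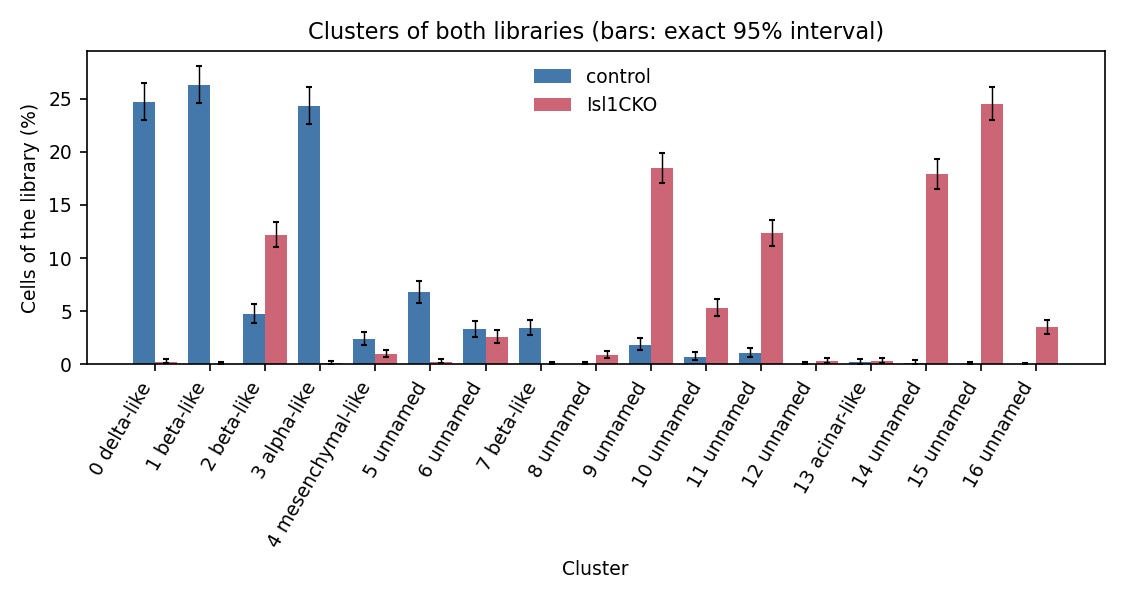
Percent of cells of each library (vertical axis) in each of the 17 clusters (horizontal axis), with exact 95% intervals. Control cells lie mostly in delta-like, beta-like and alpha-like clusters, and 86.0% of Isl1CKO cells lie in unnamed ones.

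Summed over all cells, the amino acid transporter gene Slc38a5 and the secretin gene Sct were among the genes highest in the Isl1CKO library, and hormone genes of delta, gamma and alpha cells among the lowest. Slc38a5, a glutamine transporter of alpha cells, was 204 CPM in control and 7021 CPM in Isl1CKO cells, a log2 ratio of 4.52 relative to the median of all genes (4.50 to 4.55). Sct, a gut hormone gene, was 7.89 against 345 CPM, and Cartpt, which encodes the CART neuropeptide, 7.28 against 169 CPM. Npy, the neuropeptide Y gene, had 2389 UMIs in control cells and 0 in Isl1CKO cells. Its relative log2 ratio was −10.37 with a floor of 3 UMIs, and its interval reached up to −10.07. Ghsr, the ghrelin receptor of delta cells, had 303 and 5 UMIs, and Cox6a2, a cytochrome c oxidase subunit, 485 and 16 UMIs.

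The other genes with the highest ratios were Pkd1l3, of the polycystin family, Ttyh1, Fndc1, C1ql3, Igfbp3, which encodes an insulin-like growth factor binding protein, Vstm2a and Fxyd5, a regulator of the sodium pump. Their relative log2 ratios ran from 4.13 for Fxyd5 to 6.87 for Pkd1l3, the latter from 1 control UMI (interval 4.38 to 12.19). The other genes with the lowest ratios were Sst, Reg4, Ppy, Gcg, Ntf3, the neurotrophin 3 gene, Areg, the amphiregulin gene, and Kcnj12, an inward rectifier potassium channel. Their relative ratios ran from −5.73 for Kcnj12, with 0 UMIs in Isl1CKO cells, to −8.52 for Reg4 (−10.40 to −7.16). Reg4, a regenerating-family lectin gene, had 885 control UMIs and 4 Isl1CKO UMIs.

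Of 14374 genes compared, 2467 had a CPM at least 2-fold higher and 501 at least 2-fold lower in Isl1CKO cells, 83.1% higher. The median gene was 0.58 higher on the log2 scale, because hormone transcripts take fewer of the UMIs. Relative to that median, 758 genes were higher and 982 lower. With hormone, mitochondrial, acinar and erythroid genes left out of CPM the higher share was 22.6%, with ratio-of-median scaling 43.6% and with the mean of per-cell CPM 68.9%. These sums mix the makeup of a library with levels within cells.

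Among lists fixed beforehand, the genes of delta identity lay lowest over all cells, with a relative median log2 ratio of −5.09. Counted against the median gene, as in every list here, 5 of 6 were at least 2-fold lower. Beta maturation genes had a median of −2.002, with 16 of 22 lower. Mafa, a regulator of insulin transcription, was 1.81 against 0.0515 CPM, and Ucn3, which marks mature beta cells, 91.7 against 12.4 CPM. Both medians lay at percentile 0 of 10000 matched random lists, as did islet hormones at −3.28, insulin and glucagon signalling at −0.76 and cell adhesion and islet architecture at −0.67. The bootstrap interval of cell adhesion and islet architecture includes 0 (−1.09 to 0.26). Delta identity turned to 0.64 with several-hormone cells removed, and insulin and glucagon signalling to 0.011 when thinned to 2000 UMIs. Robo2, an axon guidance receptor of islet architecture, was 37.1 against 12.0 CPM. Alpha identity genes split, with 5 of 12 higher, such as Ttr, the transthyretin gene, at 6663 against 62559 CPM, and 3 lower. The list's median was 0.25, at percentile 68.4.

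Granule and prohormone processing genes had a median of 0.50 (percentile 99.1, bootstrap −0.11 to 1.06). Chgb, the chromogranin B gene, was 2764 against 17942 CPM, and Vgf 21.2 against 261 CPM, while Scg2, the secretogranin 2 gene, was lower at 1766 against 465 CPM. Unfolded protein response genes had a median of 0.48 (percentile 99.7, bootstrap −0.020 to 0.68), with 1 of 14 at least 2-fold higher. Oxidative phosphorylation genes had a median of 0.42 (percentile 97.4), with 0 of 19. Both medians changed sign, to −0.27 and −0.064, when cells with several hormones were removed. Immature or disallowed genes had a median of −0.51, endocrine transcription factors −0.16, exocytosis −0.09, immediate early genes −0.24 and other peptides −0.32, at percentiles from 0.01 to 4.29. The bootstrap intervals of these medians all include 0. With several-hormone cells removed, immature or disallowed genes turned to 1.74, endocrine transcription factors to 0.079, exocytosis to 0.12 and proliferation to −0.48. Excitability (−0.02), proliferation (0.20), glycolysis (0.20) and erythroid transcripts (−0.43) had percentiles of 26.4, 95.4, 83.2 and 1.06. The erythroid median was −8.08 with several-hormone cells removed and −7.82 in Y-only cells.

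Within beta-like cells, Npy was not counted in the Isl1CKO library, and insulin transcripts were lower against other transcripts, a difference that did not hold for Ins1 in the cluster both libraries share. Ins1 was 219803 CPM in control and 214154 CPM in Isl1CKO beta-like cells, and Ins2 was 436875 and 303530 CPM. Over non-hormone UMIs Ins1 was 721023 and 482539 CPM and Ins2 1433090 and 683923 CPM. In cluster 2 alone, the relative log2 ratio was 0.15 for Ins1 and −0.38 for Ins2. Npy had 2363 UMIs in control and 0 in Isl1CKO beta-like cells, a relative log2 ratio of −8.48 against the floor (interval up to −8.18). Cox6a2, a marker of mature beta cells, had 473 and 0 UMIs, a ratio of −6.16 against the floor (interval up to −5.85). Pros1, the protein S gene, was 0.677 against 22.5 CPM, a relative log2 ratio of 4.63 (4.06 to 5.26). In cluster 2 alone Pros1 had a relative ratio of 2.28, and Npy, a leading gene of cluster 1, and Cox6a2 had too few UMIs there. These values come from 838 control and 367 Isl1CKO cells. Of these, 640 control cells lie in cluster 1 and 83 in the cycling-led cluster 7. In turn 364 Isl1CKO cells lie in cluster 2, whose leading genes include Msln and the B-cell antigen receptor gene Cd79a. Cells with Xist and no Y-linked UMIs were 183 of the control and 225 of the Isl1CKO beta-like cells, so the sexes are also unequally mixed. Over the whole libraries such cells were 18.2% and 32.8%.

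The other genes with the highest ratios in beta-like cells were Cidea, a lipid droplet protein gene, Cacna2d3, a calcium channel subunit, Asic2, an acid-sensing ion channel, Nlgn1, the neuroligin 1 gene, Dnah11, Ppp1r14c, Vstm2a, Dmrta1 and Wfdc16. Their relative log2 ratios ran from 3.46 for Wfdc16 to 5.41 for Cidea. The other genes with the lowest ratios included Loxl2, a lysyl oxidase, at −7.28, Dapl1 at −6.60, Ntrk2, the BDNF receptor, at −5.22 and P2ry1, a purinergic receptor, at −4.69. Ckap2l, with 182 and 0 UMIs, and Hmmr, with 477 and 6 UMIs, encode mitotic spindle proteins. Gcg at 654 against 5.56 CPM and Sst at 87.0 against 1.71 CPM also ranked lowest, but such hormone RNA also occurs outside its cells. Over non-hormone UMIs, control beta-like cells held Gcg at 2146 and Sst at 286 CPM, and control mesenchymal-like cells 1237 and 1444 CPM.

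Of 9775 genes compared in beta-like cells, 1154 had a CPM at least 2-fold higher and 265 at least 2-fold lower in the Isl1CKO library, 81.3% higher around a median of 0.42. Relative to that median 492 were higher and 463 lower. The higher share was 42.6% without hormone, mitochondrial, acinar and erythroid genes in CPM and 51.4% with ratio-of-median scaling. In cluster 2 alone, which both libraries share (115 and 364 cells), 261 of 7821 genes were higher and 49 lower, a comparison chosen after the data were seen. The control sum there was 4391837 UMIs and the Isl1CKO sum 13343335. A gene could thus enter as higher at a lower CPM than as lower, which tilts this split toward higher genes.

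Beta maturation genes lay lower in Isl1CKO beta-like cells, with a relative median of −0.78 (percentile 0) and 9 of 21 at least 2-fold lower, though Ucn3, G6pc2 and Trpm5 also lead cluster 1, which is almost all control cells. Ucn3 was 157 against 62.5 CPM, G6pc2, a glucose-6-phosphatase of beta cells, 297 against 140 CPM, and Trpm5, a cation channel, 46.8 against 12.1 CPM. Mafa was 3.16 against 0.297 CPM and Glp1r, the GLP-1 receptor, 6.24 against 1.85 CPM. In cluster 2 alone Ucn3 stood at 59.4 and 60.4 CPM and Trpm5 at 10.7 and 11.9 CPM, the list's median was −0.14, and Mafa and Glp1r had too few UMIs. Immature or disallowed genes had a median of 1.78 (percentile 100; bootstrap −1.64 to 2.94), with 4 of 8 higher and 2, Npy and Cck, lower. The higher ones are Aldh1a3, an aldehyde dehydrogenase of immature beta cells, at 0.652 against 5.19 CPM, Fev at 6.94 against 71.4 CPM, Neurog3, the endocrine progenitor regulator, at 1.23 against 9.87 CPM, and Gast, the gastrin gene, at 1.73 against 22.3 CPM. Alpha identity genes had a median of 0.99 over 7 genes (percentile 99.99; bootstrap −0.60 to 1.52), with 3 higher and 1 lower. In cluster 2 alone the medians of these lists were 0.27, with 1 of 5 immature or disallowed genes higher, and 0.19. Cluster 2 was formed by likeness over both libraries, so a smaller difference there is partly built in. Fewer immature or disallowed genes were also measured in it. These medians thus do not separate genotype from the different clusters of the 2 libraries.

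Excitability genes had a median of 0.59 (percentile 99.98) with 5 of 13 higher, such as the calcium channel subunits Cacna1a at 16.2 against 49.5 CPM and Cacna2d1 at 59.5 against 183 CPM. In cluster 2 alone that median was 0.10, with 0 of 12 higher and 1 lower. Granule and prohormone processing (0.27) and exocytosis (0.23) lay at percentiles 97.8 and 98.8, and Chgb was 1528 against 9396 CPM, while in cluster 2 alone the medians were 0.024 and −0.020. Unfolded protein response genes lay lower at −0.41 (percentile 0.02), with Creld2, a reticulum stress gene, at 67.6 against 39.4 CPM, and at −0.45 in cluster 2 alone. Proliferation genes had a median of −2.98 with 11 of 11 lower, including Mki67 at 18.6 against 1.11 CPM and Top2a at 3.48 against 0.0742 CPM. The cycling beta-like cluster 7 is almost all control cells, 77 Isl1CKO cells lie in the unnamed cycling cluster 6, and in cluster 2 alone 0 proliferation genes had enough UMIs. Thinned to 2000 UMIs, beta-like cells with a UMI of a proliferation gene were 4.77% of control (3.43 to 6.44) and 1.36% of Isl1CKO cells (0.444 to 3.15), and 18.7% and 9.26% before thinning. In delta-like control cells the thinned share was 0.832%, at a median depth of 13986 UMIs, and the Isl1CKO share is not separated from it.

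Of the remaining lists in beta-like cells, islet hormones had a relative median of −0.70, other peptides −1.41, immediate early genes −0.39 and endocrine transcription factors 0.10, against −0.21, −0.028, 0.41 and 0.032 in cluster 2 alone. Glycolysis (−0.06), oxidative phosphorylation (−0.13), insulin and glucagon signalling (−0.10) and cell adhesion and islet architecture (0.20) held 0, 0, 3 and 1 genes at least 2-fold different. Haemoglobin genes had a median of −8.51 over 3 genes, with Hba-a1 at 161 against 0.593 CPM. Hba-a1 is also a leading gene of cluster 1, and control alpha-like cells held it at 0.576 CPM. Delta identity was too sparsely measured, with 2 genes.

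**Figure D3:**
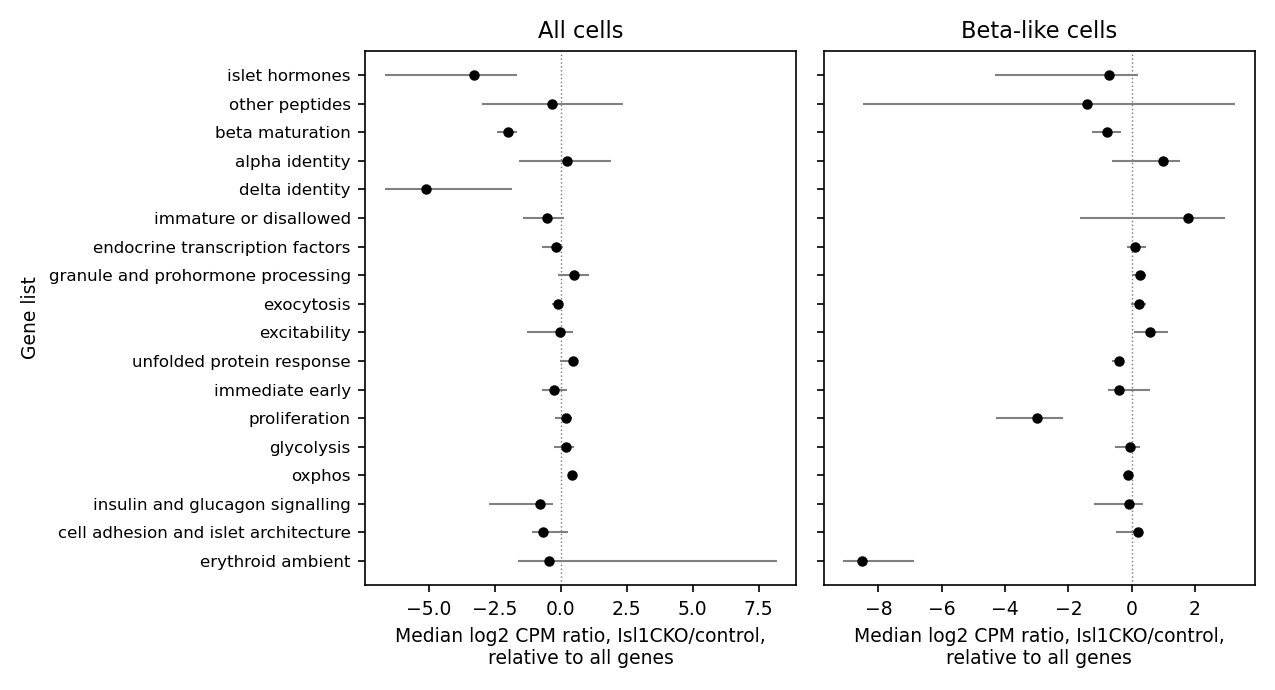
Median log2 CPM ratio of Isl1CKO over control for each fixed gene list, relative to all genes (horizontal axis), for all cells (left) and beta-like cells (right); bars are bootstrap intervals over the list's genes. Beta maturation lies at −2.002 over all cells and −0.78 in beta-like cells.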

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

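Signal appeared in control droplets outside the cells compared, which serve only as the background profile of 1 alternative. Among control barcodes with 1 to 100 UMIs, 63.1% of UMIs were islet hormone transcripts, led by Ins2 at 30.9%, Ins1 at 16.5% and Gcg at 4.74%, against 53.3% in control cells. The Isl1CKO matrix was already filtered, so its droplets below the cell threshold were not analysed here, and no biological explanation was tested.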

How the results depend on the processing

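The 2 libraries allow no spread between replicates, so a value counts as kept when it stays within its counting interval (for lists, the bootstrap interval over member genes) or, for gene counts, within 1.5 times. No paired analysis was possible because each genotype has 1 library and the 6 in both titles is the number of animals pooled. Of 18 planned and 3 added settings, the added ones (10000 expected cells, the shared beta-like cluster, and beta-like cells without the cycling cluster) were chosen after seeing the data. Over them, 52 class shares, 46 gene counts, 16 Isl1 ratios, 510 list medians and 435 single-gene ratios were kept. Another 131 single-gene ratios moved with no reversal. The cause was not tested unless stated. List medians and single-gene ratios were taken against the median gene, so settings that only change the scaling total could not move them. The single genes were those ranked highest or lowest in these same data, so a reversal was hardly possible. These tallies are therefore no independent check. Depth limits genes near the 50-UMI minimum and classes with few Isl1CKO cells, and thinning to 2000 UMIs left too few Isl1CKO beta-like cells for beta-like values. With background subtracted (1.80% of control and 2.92% of Isl1CKO UMIs), too few UMIs of Gcg and Sst were left in beta-like cells for a value. The background profile came from control droplets for both libraries, since none are held for Isl1CKO. A maximum of 8% mitochondrial UMIs also changed doublet calls, from 62 to 11 control cells.

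Without the mitochondrial filter, Isl1CKO beta-like cells were 9.47%, 710 genes were higher in beta-like cells and the Isl1 log2 ratio there was 0.85. With doublets kept, beta-like and alpha-like Isl1CKO shares were 9.84% and 0.435%, 737 genes were higher in beta-like cells and the Isl1 ratio there was 0.86. The alpha-like Isl1CKO share was 0.402% with 10000 expected cells, 0.436% at resolution 0.5 and 0.369% with hormones left out of clustering, where the beta-like proliferation median was −1.998. At resolution 2 the Isl1CKO beta-like share was 9.62%, alpha-like shares were 27.0% in control and 0.603% in Isl1CKO, 728 genes were higher in beta-like cells and the Isl1 ratio was 0.91. With each library clustered alone, the Isl1CKO beta-like share was 7.11%, the control alpha-like share 27.5%, and Isl1CKO alpha-like and delta-like shares were 0 and 0. There 527 beta-like genes were higher, the Isl1 ratio was 0.73, and unfolded protein response and proliferation medians were −0.26 and −5.17.

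Removing cells with several hormones left 1331 control and 1166 Isl1CKO cells. The rule sets each hormone type against a cell's own hormone UMIs, at 5%, and not against all its UMIs. With a median hormone share of 0.632% in Isl1CKO cells, a few UMIs of carried hormone RNA can pass it. Removal there thus need not mean that a cell makes several hormones. Cells keep their class here, so nearly all delta-like cells went because they passed this rule. Beta-like shares became 61.5% and 28.9% and delta-like shares 0.150% and 0. There 190 genes were lower over all cells and the Isl1 ratio was 1.21. List medians over all cells became −1.57 for beta maturation, 1.74 for immature or disallowed, 0.079 for endocrine transcription factors, 0.12 for exocytosis, −0.27 for unfolded protein response, −0.48 for proliferation, −0.24 for insulin and glucagon signalling and −8.08 for erythroid genes. Of these, the medians of immature or disallowed, endocrine transcription factor, exocytosis, unfolded protein response and proliferation genes changed sign. Delta identity reversed to 0.64 and oxidative phosphorylation to −0.064. Thinned to 2000 UMIs, beta-like shares were 29.0% and 0.771%, 844 genes were higher and 189 lower over all cells, and the Isl1 ratio was 0.48. The medians were −1.59 for beta maturation and 0.30 for oxidative phosphorylation, and insulin and glucagon signalling reversed to 0.011. Thinning leaves fewer genes past the minimum count by construction.

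In Xist-only cells, control and Isl1CKO shares were 41.3% and 23.0% beta-like, 29.1% and 0 alpha-like, and 19.6% and 0.102% delta-like. There 194 genes over all cells and 141 in beta-like cells were lower, beta maturation was −1.48 and immature or disallowed 1.35 over all cells, and beta-like proliferation was −5.40. In Y-only cells the Isl1CKO beta-like share was 6.35%, Isl1 ratios were 0.96 over all cells and 1.43 in beta-like cells, and the erythroid median was −7.82. With hormone, mitochondrial, acinar and erythroid genes left out of CPM, 470 genes were higher and 1612 lower over all cells, and 419 and 564 in beta-like cells. The Isl1 ratio reversed to −0.059 over all cells and was 0.64 in beta-like cells, because the hormones no longer enter the total. With ratio-of-median scaling 760 genes were higher and 982 lower over all cells, 491 and 464 in beta-like cells, and the Isl1 ratios were 0.28 and 0.75. With the mean of per-cell CPM 1339 genes were higher, the Isl1 ratios were 0.45 and 1.29, and beta maturation was −1.65. With background subtracted the beta-like erythroid median was −9.87. At 20 UMIs 453 beta-like genes were lower, and at 200 UMIs 244 genes over all cells and 102 in beta-like cells were lower and 498 in beta-like cells higher, since fewer genes are compared. In the shared beta-like cluster, where the minimum count tilts the split, 261 genes were higher and 49 lower. There the Isl1 ratio was 1.93, beta maturation −0.14 and exocytosis −0.020.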

Other observations

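Isl1CKO cells of the Gcg-low clusters held alpha-cell transcripts with little Gcg. They were set against control alpha-like cells, a comparison chosen after the data were seen. Gcg was 272400 CPM in the control cells and 1838 CPM in the Isl1CKO cells, and Pou3f4 58.5 against 4.20 CPM. Ttr was 28446 against 101946 CPM, Slc38a5 895 against 11749 CPM, and Irx1, an Iroquois homeobox gene, 153 against 261 CPM, though Ttr, Slc38a5 and Irx1 are also markers by which these clusters were grouped. Unfolded protein response genes had a relative median log2 ratio of 1.34 (percentile 100) with 9 of 14 at least 2-fold higher, such as Sdf2l1 at 43.2 against 343 CPM. Proliferation genes had a median of 3.38 with 11 of 12 higher, since cycling clusters are among those compared, and immediate early genes a median of −1.27. Relative to the median gene, 1107 genes were higher and 754 lower among 11867, and over non-hormone UMIs 749 were higher and 1556 lower. The control alpha-like sum was 12145756 UMIs against 43122586, so the minimum count let in higher genes at a lower CPM.

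The remaining Isl1CKO cells, set against Isl1CKO beta-like cells in a comparison also chosen after the data were seen, fell largely in clusters 9 and 11. Cluster 9 is led by haemoglobin genes, and its Isl1CKO cells were higher in erythroid genes (relative median 8.80, 4 of 4) and acinar genes (1.72, 14 of 14), while 2 of 6 progenitor markers were at least 2-fold higher. Chgb is a leading gene of cluster 11, while Reg4 leads it through its control cells, with 865 UMIs against 0 in its Isl1CKO cells. There, 2 of 3 enterochromaffin markers and 3 of 6 progenitor markers were at least 2-fold higher in the Isl1CKO cells. The bootstrap intervals of the progenitor and enterochromaffin medians include 0, and these genes also describe the clusters. Immediate early genes were higher too, with relative medians of 1.69 in cluster 9 (7 of 10) and 1.25 in cluster 11 (5 of 8). Of 10 alpha markers, 5 were at least 2-fold higher and 2 lower in cluster 9, and 2 of 3 delta markers were higher. In cluster 9, 551 Isl1CKO cells held Neurog3 at 107 CPM, Fev at 480 CPM, Tac1, the tachykinin gene, at 129 CPM and Gast at 296 CPM. In cluster 11, 368 Isl1CKO cells held Neurog3 at 60.5 CPM, Fev at 411 CPM and Chgb at 71920.1 CPM. Isl1CKO beta-like cells held Neurog3 at 9.87 CPM and Fev at 71.4 CPM. Ins1 was 3879 CPM in cluster 9 and 30904 CPM in cluster 11, and Ins2 16247 and 36179 CPM. Beta maturation genes lay below Isl1CKO beta-like cells in both, with relative medians of −2.16 and −2.30. The list shares genes such as Ins1, Ucn3 and Slc2a2 with the markers that named beta-like cells, so lower medians partly restate the naming.

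Of the tests that follow, the matched-depth one and the Xist CPM one were written before their results were seen, and the others after.

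Isl1CKO cells with Xist and no Y-linked UMIs were beta-like in 23.0%, against 6.35% of cells with Y-linked and no Xist UMIs, and control cells in 41.3% and 33.8%. Isl1CKO shares went the other way in cluster 11, at 3.27% and 17.4%, and in cluster 9, at 11.6% and 21.7%. In the Gcg-low clusters they were 57.1% and 49.5%. Depth is argued against for the beta-like cells. Between 10000 and 25000 non-hormone UMIs their Isl1CKO shares were 42.0% (37.7 to 46.4) and 9.57% (7.88 to 11.5). In that window the shares were 5.13% and 25.7% in cluster 11 and 20.5% and 31.6% in cluster 9. In the Gcg-low clusters they were 30.2% (26.2 to 34.4) and 31.3% (28.5 to 34.1), so the difference did not hold there. Free Xist RNA was to give an Xist CPM ratio of beta-like to other Xist-only cells under 0.5, and the ratio was 0.447, but that bound was badly set, because insulin RNA lowers every CPM in beta-like cells. Over non-hormone UMIs the ratio was 1.06 (1.00 to 1.11), and 5.83% of beta-like cells with Y-linked UMIs held Xist (2.38 to 11.6) against 61.3% Xist-only among beta-like cells, so free RNA is argued against. A sex difference in the Isl1CKO animals may contribute, but it cannot be told apart from unequal numbers of beta-like cells among the 6 pooled animals, whose cells carry no animal label.

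Shallow or damaged cells are argued against for the Gcg-low clusters, whose median gene number was 1.22 times that of control alpha-like cells, with a mitochondrial share 1.16 times theirs. Their ratio of Gcg to Ttr UMIs was 0.188% of that in control alpha-like cells, but it restates how the clusters were set apart and decides nothing. Free RNA of alpha cells was tested by the level of the 5 alpha markers of these clusters, since carried RNA cannot exceed its source. Per non-hormone UMI the median ratio to control alpha-like cells was 2.28 (2.16 to 2.41), from 1.02 to 9.14. These 5 were picked for being at least 2-fold over all other cells in these clusters. A ratio above 1 was thus largely set by that choice, and the test cannot decide. Over all 10 alpha markers the relative median log2 ratio was −0.59, with 5 at least 2-fold lower and 3 higher. A candidate explanation is that these are cells of alpha lineage that lost Gcg, which the genotype could bring about, but with 1 library per genotype it stays untested.

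For the higher Isl1 counts, the increase over all cells vanished per non-hormone UMI, with a log2 ratio of −0.054 (−0.08 to −0.03). That sum mixes classes that differ in share and direction. Per non-hormone UMI, Isl1 was 262 CPM in control and 406 CPM in Isl1CKO beta-like cells. Control alpha-like cells held 683 CPM and Isl1CKO Gcg-low cells 513 CPM. The smaller hormone share thus cannot be told apart from class makeup over all cells. For beta-like cells the hormone share is argued against, since that log2 ratio was 0.63 (0.56 to 0.71), and 1.82 in cluster 2 alone. Whether the counted tags lie outside the deleted part cannot be told apart from incomplete deletion, because the labels name no exon and Isl1 stood at 459 CPM over all Isl1CKO cells. A loss of feedback of the protein on its own gene may also raise these counts, and was not tested.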
